A study of Mus musculus with 6 samples.

How the data were processed

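The samples are 6 poly(A)-selected, strand-specific mRNA libraries, 2 each of shCtrl, shPnky and shPtbp1, grouped by the shRNA named in the labels. Per the submitters' processing notes, the genome build was mm9 and the tools included TopHat2 2.0.10, Cuffdiff 2.1.1, TopHat, Cufflinks and Cuffnorm, with no role given. The counting program, the bin annotation and the version of DEXSeq, the exon usage test named by the deposited files, are not given in the sources used here. The authors deposited 1 table per knockdown, restricted to bins with an adjusted p under 0.01. Per the file headers, each row gives the authors' p-value and adjusted p-value of a likelihood ratio test, a log2 fold, and raw counts for 4 libraries. The deposited fitted usage values, dispersion and test statistic are scores of the authors' model. The listed mean equals the mean of the 4 raw counts, and the log2 fold equals the log2 ratio of the fitted usage values.

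Bin numbers were read from row names, because 52 bin labels of the shPtbp1 table had lost a trailing zero. Of the shPtbp1 bins, 13 had no listed fold and stayed out of counts of direction. An adjusted p of 0 was listed for 4 shPtbp1 bins. Gene identifiers are Entrez numbers: 175 of 175 and 598 of 602 matched a current symbol in a GRCm38 gene table, used only for names and strand. The symbols printed are those of the files. No coordinates are given, because the tables hold none and the reference has another build. For this reason the share of bins with a length divisible by 3 and the overlap of bins by position were not computed. The numbers of tested bins, 160603 for shPnky and 160290 for shPtbp1, were recovered from p and adjusted p.

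The plan, fixed before the data were examined, took the authors' calls as the main result and assumed that no counts per library were held. The tables did hold counts, so count tests were added after seeing them. In edgeR 4.0.16 (R 4.3.3), each bin was tested against the other listed bins of its gene at an adjusted p under 0.01, with TMM scaling, and changes in bin counts were tested with glmQLFTest. DESeq2 1.42.0 was an alternative. These tests see only bins the authors had already called, so they are no independent evidence, and their scaling rests on called bins: the median log2 count change of all shPtbp1 bins was 0.02. Tested on simulated data with bins changed by a log2 fold of 1, the test within genes recovered 52 of 80 bins over 516 shPtbp1 bins and 10 of 16 over 107 shPnky bins. It called 2 of 260 and 0 of 66 bins of genes without a changed bin. The simulated data had a fixed dispersion above the medians of the authors' model (0.00041 for shPtbp1, 0.00024 for shPnky), so these rates need not hold in the data. The count test recovered 190 of 191 bins in 958 shPtbp1 bins.

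Shares are the percent of a gene's listed reads, with the SD of 2 libraries. They leave out uncalled bins, so with few listed bins a share can move against the listed fold. Median counts per bin were 946 (shPtbp1) and 1713 (shPnky). Replicates differed by more than sampling noise (chi-square over degrees of freedom 2.45 to 7.76), so none was treated as a duplicate. Directions were tested with two-sided exact binomial tests on 1 bin per gene, overlaps with hypergeometric tests and 1000 simulated pairs of null statistics with a correlation of 0.5, fold correlations with 100000 permutations, and 13 gene lists (593 genes, 55 in more than 1 list) with Fisher's exact test (Python 3.11.15, scipy 1.17.1). The lists were written beforehand: textbook PTBP1 targets, splicing factors, actin and adhesion, microtubule and axon, synapse and trafficking, chromatin, 5 sets of cell type markers, signalling and a control list.

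The leading bin of a gene is its bin with the smallest adjusted p. Where a gene is given as higher or lower, only its leading bin is meant, because other bins of the gene can go the other way. The genes named were fixed by rule: per table the 10 genes whose leading bins had the smallest adjusted p in each direction and the 5 largest and 5 smallest folds (1 bin per gene), up to 20 genes called in both, up to 4 members per list and table, and Ptbp1, Ptbp2, Ptbp3, Pnky and Pou3f2 whatever their values. Some genes that meet the rule are not reported here. Qk, and the bins shown for opposite directions, were chosen after their values were seen. Alternatives were an adjusted p under 0.001, a mean count of at least 50, an absolute log2 fold of at least 1, all bins against 1 per gene, other scalings, a replicate block and leaving out each library.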

Results

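RNA was sequenced from 6 libraries of cultured mouse ventricular-subventricular zone cells, the neural stem cell niche of the postnatal forebrain, taken at postnatal day 5 to 7 and grown in medium with EGF and FGF. The cells carried a short hairpin RNA against luciferase (shCtrl), against the long noncoding RNA Pnky (shPnky) or against Ptbp1 (shPtbp1), which encodes an RNA-binding protein that represses many neuronal exons, and were sorted for the fluorescent marker of the vector. Each group had 2 libraries. The labels do not say that replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. The authors' deposited table for each knockdown lists the exon bins (exons or parts of exons, numbered within a gene) whose relative usage differed from shCtrl at an adjusted p under 0.01, together with the raw count of each bin in each library. The counts of the shPtbp1 table summed to 3920040 and 3514859 in shCtrl and to 3628672 and 3559229 in shPtbp1. Those of the shPnky table summed to 2047794 and 1838898 in shCtrl and to 2403866 and 1727096 in shPnky. These sums cover called bins and are not library sizes. Bins carry no coordinates in the tables, so a bin is named here by gene and number, and a gene's first bin, which has no number, is called its unsuffixed bin.

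The targeted gene was examined first. In the authors' deposited table for shPtbp1, bin 13 of Ptbp1 (Entrez 19205) held 22334 and 19594 reads in the shCtrl libraries and 4967 and 4961 in the shPtbp1 libraries. Its count fell by 2.14 on the log2 scale (SE 0.035, edgeR quasi-likelihood test over the listed bins, adjusted p = 7.35e-28). The paralog Ptbp2, a neuronal family member whose transcript is a known PTBP1 target, moved the other way. Its bin 4 rose from 313 and 290 reads to 673 and 700, a log2 count change of 1.13 (SE 0.084, edgeR adjusted p = 8.71e-13), and its unsuffixed bin from 5760 and 5423 to 9075 and 9007, a log2 count change of 0.63 (SE 0.037, edgeR adjusted p = 3.93e-15). Within Ptbp2, the usage of bin 4 was higher (log2 fold 0.18) and that of the unsuffixed bin lower (log2 fold -0.05) in the authors' deposited table. No bin of Pnky, Ptbp3 or Pou3f2 was called in either table, and none of Ptbp1 or Ptbp2 in the shPnky table, so the knockdown of Pnky could not be checked from the called bins.

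The first comparison asked which exons change their usage when Ptbp1 is depleted. The largest shifts by adjusted p included lower usage of the unsuffixed bin of Tpm1 (Entrez 22003), which encodes an actin-binding tropomyosin: its reads fell from 7455 and 6437 to 1690 and 1510, and its share of the reads in the 11 listed Tpm1 bins went from 31.0% ± 1.12 (SD, n = 2) to 7.55% ± 0.25 (SD, n = 2). Bins 2 and 3 of the same gene rose from 5.57% ± 0.11 to 12.3% ± 0.11 and from 4.85% ± 0.17 to 11.6% ± 0.30 (SD, n = 2). The unsuffixed bin of Ncam1, a neural cell adhesion molecule, fell from 24.8% ± 0.25 to 9.02% ± 0.21 of the reads in its 14 listed bins, and bin 3 of Rtn4, which encodes the reticulon Nogo, rose from 17.4% ± 0.43 to 32.9% ± 1.00 of 8 listed bins (SD, n = 2).

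In all, the authors' deposited table for shPtbp1 lists 958 bins in 602 genes. Of the 945 bins with a fold, 516 had higher and 429 lower usage in shPtbp1. The bin with the smallest adjusted p was higher in 283 genes and lower in 307 (48.0% higher, two-sided exact binomial p = 0.344). Usage is relative within a gene: of 160 genes with at least 2 listed bins, 130 had bins in both directions. Among the bins with an absolute log2 fold of at least 1, counted once per gene, 23 of 28 were higher (82.1%, two-sided exact binomial p = 0.000912). The median absolute log2 fold was 0.16. The listed fold is the log2 ratio of the authors' fitted usage values and not of counts: within genes, the count change was 2.11 times the listed fold (median of 406 bins, 95% bootstrap interval 2.09 to 2.13).

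Counting only the leading bin of each gene, the genes that led the higher bins by adjusted p were Synpo, an actin-associated protein of dendritic spines (bin 1, log2 fold 0.29), H13, a signal peptide peptidase (bin 11, 0.69), Rtn4 (bin 3, 0.37), Ap2a1, a subunit of the AP-2 endocytic adaptor (bin 8, 1.68), and Slc44a1, a choline transporter (bin 16, 0.39), all from the authors' deposited table. Aplp2, Ensa, Rufy3, Rapgef1 and Pdlim5 followed, with log2 folds of 0.31, 0.08, 0.31, 1.61 and 0.76 in the authors' deposited table. Bin 8 of Ap2a1 went from 41 and 32 reads to 305 and 302, and bin 12 of Rapgef1, a guanine nucleotide exchange factor, from 51 and 52 to 332 and 373. The lower leading bins were headed by those of Lrrfip1 (bin 19, log2 fold -0.22), Ncam1 (-0.61), Tpm1 (-0.98), Dclk1 (bin 7, -0.10) and the tropomyosin gene Tpm3 (bin 5, -0.50) in the authors' deposited table. Emc1, Zak, Gnao1, Map4 and Seh1l followed, with log2 folds of -0.18, -0.69, -0.15, -0.43 and -0.12 in the authors' deposited table. Of the 5 most positive folds, counting 1 bin per gene, 3 belonged to bins without a read in shCtrl: Plec bin 31 (8 and 14 reads in shPtbp1), Pum2 bin 5 (10 and 10) and Pde4dip bin 45 (13 and 7). The other two were Pdlim5 bin 10 (4 and 1 reads to 59 and 67) and Lrrfip1 bin 4 (4 and 2 to 118 and 79). Counting 1 bin per gene, the most negative log2 folds in the authors' deposited table were those of Tpm1 bin 7 (-1.29), Pdlim7 bin 4 (-1.20), Dnah7b bin 1 (-1.15), Cacna1g bin 14 (-1.14) and Tmem87a bin 9 (-1.12). Those of Dnah7b and Cacna1g rest on 16 reads or fewer per library.

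Of 41 genes listed beforehand as textbook PTBP1 targets, 20 had a called bin in shPtbp1, with the leading bin higher in 15 and lower in 5. The 15 include Ptbp1 itself, the target of the hairpin, whose bin 13 had a log2 fold of usage of 0.03 in the authors' deposited table while its reads fell. Examples from the authors' deposited table are Clta, a clathrin light chain (bin 4, log2 fold 1.01), Rtn4 (0.37), Tpm1 (-0.98) and the kinesin gene Kif1b (bin 27, -0.23). Among 86 actin cytoskeleton and adhesion genes, 25 were called, 13 with a higher and 12 with a lower leading bin. The leading bin of Pdlim5 rose and those of Ncam1, Tpm1 and Tpm3 fell. Among 83 synapse, vesicle and membrane trafficking genes, 15 were called, 9 higher, 5 lower and Syt1 without a listed fold. Picalm bin 12, of a clathrin assembly protein, had a log2 fold of 0.38 in the authors' deposited table. In the list of 66 signalling kinases and small GTPase regulators, 15 were called, 11 higher and 4 lower. Among those higher were Camk2b, a calcium/calmodulin-dependent kinase subunit (bin 6, log2 fold 1.05 in the authors' deposited table), Rapgef1 and Aplp2, and Gnao1 was lower. Aplp2 and Gnao1 are on this list, though they are neither kinases nor regulators of small GTPases. Of 45 microtubule, motor and axon genes, 11 were called, 8 higher and 3 lower; the microtubule-associated Map4 fell and Rtn4 rose. Of 90 splicing factors and RNA-binding proteins, 8 were called, 6 higher (Ptbp1 included) and 2 lower, among them Luc7l2 bin 8 (log2 fold 0.03), Luc7l bin 9 (-0.07) and Celf1 bin 14 (-0.10) in the authors' deposited table. Chromatin and transcription regulators gave 9 of 71, with 6 higher and 3 lower; Camta1 (log2 fold 0.53) and Nfia (0.03) rose and Smarca2 (-0.07) fell in the authors' deposited table. Of the control list of 40 ribosomal and housekeeping genes, 6 were called, 1 higher and 5 lower, with log2 folds of -0.07 for Rps24 and -0.03 for Eif4a2 in the authors' deposited table.

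In shPtbp1, 6 of 37 neural stem cell and astrocyte markers were called (3 higher, 3 lower), among them Aldoc (log2 fold 0.04), Fgfr2 (-0.29), Gfap (-0.03) and Egfr (-0.04) in the authors' deposited table. Of 29 transit-amplifying cell and neuroblast markers, Ncam1, Dclk1 and Meis2 were called, 3 in all, each with a lower leading bin. Other called bins of Ncam1 and Dclk1 went both ways. Examples are Ncam1 bins 3 (lower) and 4 (higher) and Dclk1 bins 1 (lower) and 19 (higher). Of 20 oligodendrocyte-lineage markers, Ptprz1 (0.16) was higher and Nfasc (-0.33) lower in the authors' deposited table. None of 25 microglial, endothelial, pericyte and fibroblast markers and none of 15 ependymal markers was called by the authors' DEXSeq test in either knockdown; values of uncalled bins were not analysed here. These calls concern relative usage of bins, not the level of a gene.

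The second comparison asked which exons change their usage when Pnky is depleted. The clearest shift was in Dclk1 (Entrez 13175), a microtubule-associated doublecortin-like kinase: bin 7 fell from 66.1% ± 0.16 (SD, n = 2) to 52.2% ± 0.18 (SD, n = 2) of the reads in its 13 listed bins, while bin 19 rose from 21.8% ± 0.18 to 31.7% ± 0.43 (SD, n = 2). In Vmp1, an autophagy membrane protein, the unsuffixed bin fell from 49.2% ± 0.34 to 39.7% ± 0.54 of 11 listed bins, and in Lrrfip1, bin 24 rose from 18.3% ± 0.13 to 24.1% ± 0.18 of 6 listed bins (SD, n = 2). Bin 1 of Acot5, an acyl-CoA thioesterase, held 2 and 4 reads in shCtrl and 421 and 382 in shPnky; Acot5 belongs to a family of close paralogs, so its reads are uncertain.

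The authors' deposited table for shPnky lists 249 bins in 175 genes, 119 higher and 130 lower. The leading bin was higher in 69 genes and lower in 106 (39.4% higher, two-sided exact binomial p = 0.00634). Of 33 genes with at least 2 listed bins, 31 had bins in both directions. The test therefore concerns which bin of a gene leads and shows no general loss of usage. Over all bins 47.8% were higher (two-sided exact binomial p = 0.526). The median absolute log2 fold was 0.11, and 5 bins reached a log2 fold of 1 in size. Within genes the count change was 2.22 times the listed fold (median of 73 bins, 95% bootstrap interval 2.09 to 2.32). Among the leading bins of genes, the higher ones were led by Lamp2, a lysosomal membrane protein (bin 1, log2 fold 0.09), Arpp19, a phosphatase inhibitor (bin 3, 0.07), Lrrfip1 (bin 24, 0.12), Pnkd (bin 11, 0.04) and the intermediate filament gene Gfap (bin 2, 0.05) in the authors' deposited table. Luc7l, Ensa, the neurotrophin receptor gene Ntrk2, Acot5 and Pigk followed, with log2 folds of 0.04, 0.04, 0.03, 0.69 and 0.14 in the authors' deposited table. The lower leading bins were headed by those of Dclk1 (bin 7, log2 fold -0.10), Vmp1 (-0.13), the transcription factor subunit gene Taf9 (bin 3, -0.05) and Zmat3 (-0.03) in the authors' deposited table. Kif1b, Tmem30a, Araf, Lcorl and Dnajc3 followed, with log2 folds of -0.16, -0.03, -0.11, -0.27 and -0.06 in the authors' deposited table. Pkd1l1 bin 29 (23 and 10 reads in shPnky) and the unsuffixed bin of Dach2 (6 and 6) had no read in shCtrl and the most positive folds, followed by Acot5, Eea1 bin 15 (31 and 41 reads to 103 and 68) and Sorbs3 bin 18 (40 and 25 to 96 and 64). Counting 1 bin per gene, the most negative log2 folds in the authors' deposited table were those of Acot5 bin 2 (-2.44), Klhdc8b bin 8 (-1.26), Gnat1 bin 2 (-1.02), 2610005L07Rik bin 1 (-0.74) and Nrcam bin 17 (-0.60). Those of Klhdc8b and Gnat1 rest on 18 reads or fewer per library. The reads of Acot5 bin 2 rose (7 and 9 in shCtrl, 15 and 13 in shPnky) while those of bin 1, the other listed bin, rose more.

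In shPnky, 5 of the 86 actin and adhesion genes were called and each leading bin was lower: Fn1 bin 21, of the matrix protein fibronectin (log2 fold -0.54), Tnc bin 13 (-0.09), Ctnnd1 bin 9, of a cadherin-associated catenin (-0.35), Tpm1 bin 3 (-0.15) and Nrcam bin 17 (-0.60) in the authors' deposited table. Fn1 bin 25, Tnc bins 16 and 24 and Tpm1 bin 7 were called higher, and Tnc bin 12 and Tpm1 bin 2 lower. The leading bins therefore show no common direction of these genes. The 3 called microtubule, motor and axon genes, Dclk1, Kif1b and Rtn4, had lower leading bins as well. In Dclk1, bins 1 and 7 were lower and all other listed bins higher. The 3 called chromatin and transcription regulators were higher, with log2 folds of 0.38 for Camta1, 0.44 for Hdac5 and 0.47 for Kmt2a in the authors' deposited table. Of the textbook PTBP1 targets 4 were called, Camta1 higher and Kif1b, Rtn4 and Tpm1 lower. Splicing factors and RNA-binding proteins gave 5, with Luc7l (0.04) and Srsf10 (0.05) higher and Luc7l2 (-0.03), Hnrnpa3 (-0.02) and Qk (-0.03) lower in the authors' deposited table. Stem cell and astrocyte markers gave 3, Gfap higher and Prom1 (-0.50) and Vim (-0.003) lower in the authors' deposited table. By leading bin, the remaining calls were Dclk1 among neuroblast markers (lower) and Ptprz1 among oligodendrocyte-lineage markers (higher). Mtor (lower) and Git1 (higher) were called among signalling genes, and Rpl5 (lower) and Tpi1 (higher) in the control list. No synapse and trafficking gene was called.

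**Figure D1:**
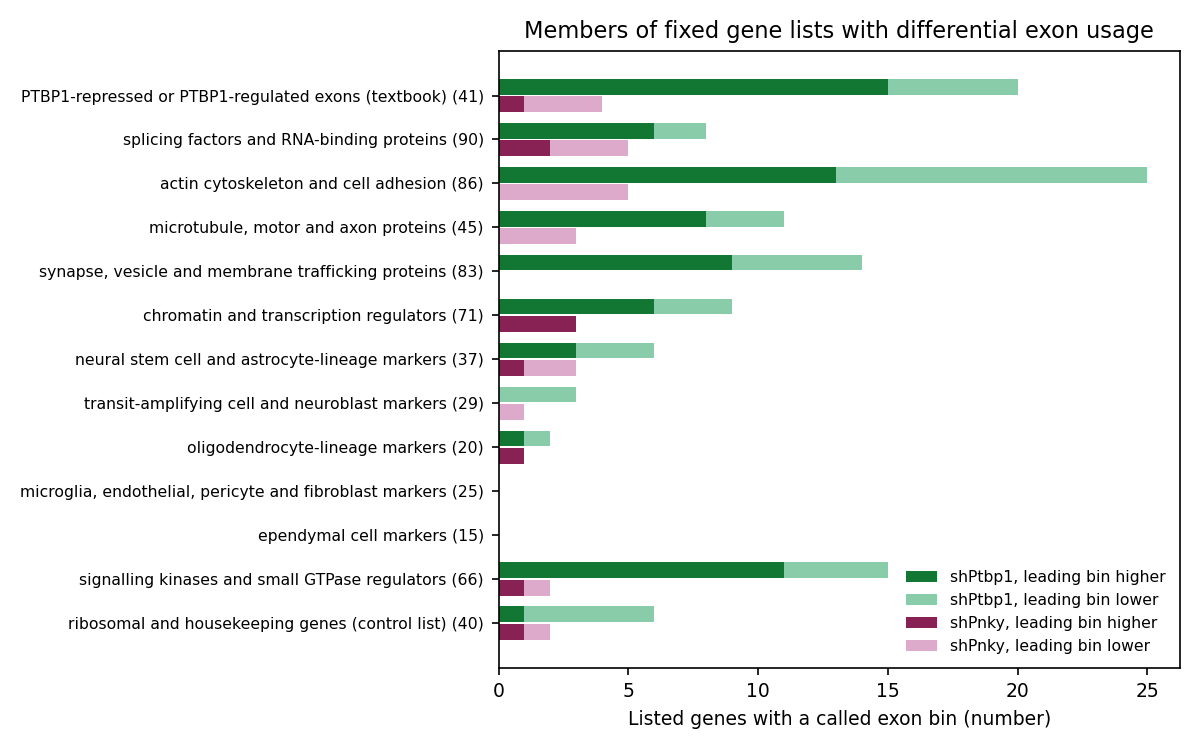
Number of genes (horizontal axis) of each list with a called exon bin in shPtbp1 and in shPnky, split by whether the leading bin was higher or lower than in shCtrl; the size of each list is in brackets, and Syt1, which has no fold, is left out. The actin and adhesion list has 25 genes called in shPtbp1 and 5 in shPnky.

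Whether a list took a different share of the called genes in the 2 knockdowns was tested with Fisher's exact test for each of the 13 lists. None of the 13 lists passed after Benjamini-Hochberg adjustment, and 1 had an unadjusted p under 0.05: synapse and trafficking genes were 2.49% of the genes called in shPtbp1 and 0% of those called in shPnky (15 of 602 against 0 of 175, two-sided Fisher's exact p = 0.0294, adjusted p = 0.382). The genes tested by the authors but not called were not analysed here, so no enrichment over expressed genes and no count adjusted over the list alone is given.

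The third comparison asked how far the exons changed by the 2 knockdowns overlap. Dclk1 bins called in both moved in the same direction: bin 7 fell from 64.8% ± 0.22 to 53.4% ± 0.30 of 14 listed bins in shPtbp1 (SD, n = 2), and its log2 fold was -0.10 in each of the authors' deposited tables. Bin 19 of Dclk1 had a log2 fold of 0.18 in shPnky and 0.15 in shPtbp1 in the authors' deposited tables, and 4 of its 13 shared bins, bins 8, 9, 10 and 19, had folds that differed between the knockdowns by a normal test with an assumed covariance (Benjamini-Hochberg adjusted over 118 bins). Lrrfip1, Taf9, Kif1b, Tmem30a, Vmp1, Ensa, Lcorl, Cadm1, Calm3, Pnkd, Arpp19 and Maoa also had a leading shared bin with the same direction in both. In all, 118 bins were called in both tables, 47.4% of the shPnky bins, against 1.49 for independent lists over 160290 tested bins (one-sided exact hypergeometric p = 3.9e-193). They included 56 bins higher in both, against 0.38 for independent lists, and 45 lower in both, against 0.35. The 118 bins lie in 71 genes, and bins of a gene share reads. The hypergeometric test takes all tested bins as independent and equally likely to be called, so its p overstates the evidence. At the level of genes, 75 were called in both, 42.9% of the shPnky genes, against 10.5 for independent lists if 10000 genes were tested. Both comparisons used the same 2 control libraries. Unchanged groups simulated against shared controls gave a mean of 0.06 bins in both and at most 2 in 1000 draws, with 100% of these few bins in the same direction. They had a mean of only 2.37 (shPnky) and 9.41 (shPtbp1) called bins, against 249 and 958 in the data. Lists so short could not share 118 bins, so the simulation cannot explain or exclude the overlap. The 2 controls were not split between the knockdowns, so part of the excess may come from the shared controls. Neither the value for independent lists nor the simulated value measures a shared effect.

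Of the 118 bins, 101 moved in the same direction (85.6%). Counting 1 bin per gene, 57 of 71 genes did (80.3%, two-sided exact binomial p = 2.67e-07). This p is against 50% and takes no account of the shared controls, under which simulated unchanged groups gave 100%, so it does not measure agreement beyond them. Across these bins, which are not independent replicates, the log2 folds of the authors' deposited tables had a Pearson r of 0.38 (permutation p = 0.00014) and a Spearman rho of 0.53 (permutation p = 1e-05, the smallest the permutations can give). The r was 0.33 without the 2 bins farthest from the median shPnky fold, and 0.25 (permutation p = 0.029) over the 76 bins with an adjusted p under 0.001 in both tables. The covariance of the folds was 0.0179, against 0.000507 from the sampling noise of the shared controls in the authors' model. The second value holds no shift of the control cultures and does not allow for the choice of bins called in both. The 2 values therefore do not show how much of the covariance comes from the shared controls.

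**Figure D2:**
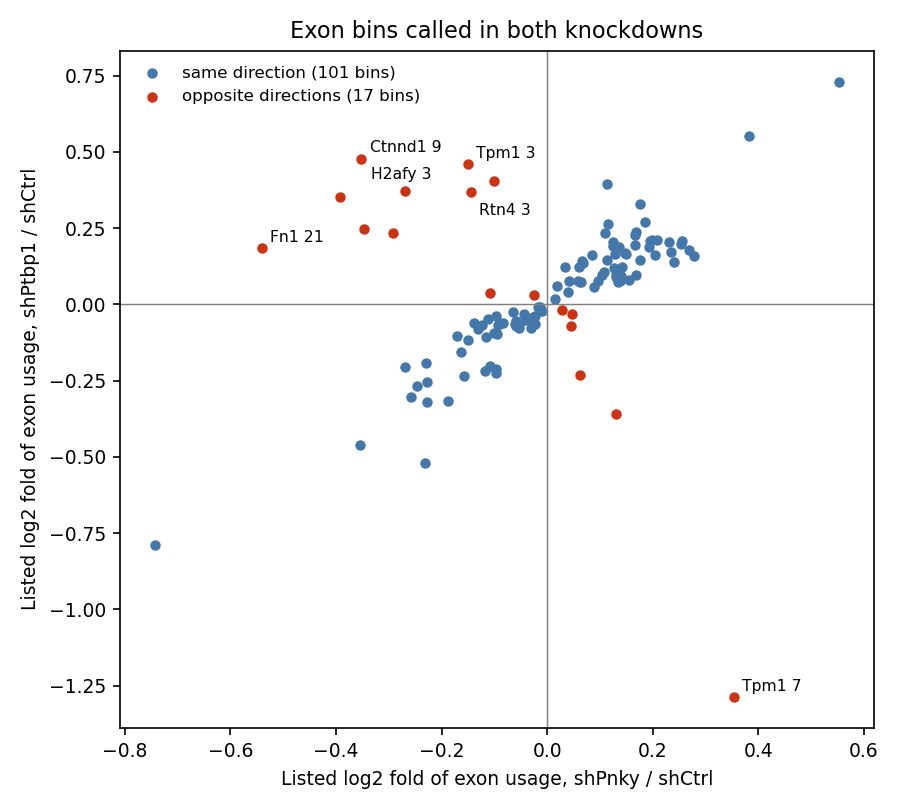
Log2 fold of exon usage against shCtrl in shPnky (horizontal axis) and in shPtbp1 (vertical axis) for the 118 exon bins called in both, from the authors' deposited tables; each point is 1 bin. The 101 bins that moved in the same direction lie in the lower left and upper right quadrants, and the 17 in opposite directions include 3 bins of Tpm1.

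The other 17 bins, in 14 genes, moved in opposite directions, 11 of them higher in shPtbp1 and lower in shPnky and 6 the reverse. In Tpm1, bins 2 and 3 were higher in shPtbp1 (log2 folds 0.40 and 0.46) and lower in shPnky (-0.10 and -0.15), while bin 7 was lower in shPtbp1 (-1.29) and higher in shPnky (0.35), by the authors' deposited tables. Rtn4 bin 3 (0.37 and -0.14), Fn1 bin 21 (0.18 and -0.54), Ctnnd1 bin 9 (0.48 and -0.35) and bin 3 of H2afy, a macroH2A histone gene (0.37 and -0.27), were higher in shPtbp1 and lower in shPnky in the authors' deposited tables.

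**Figure D3:**
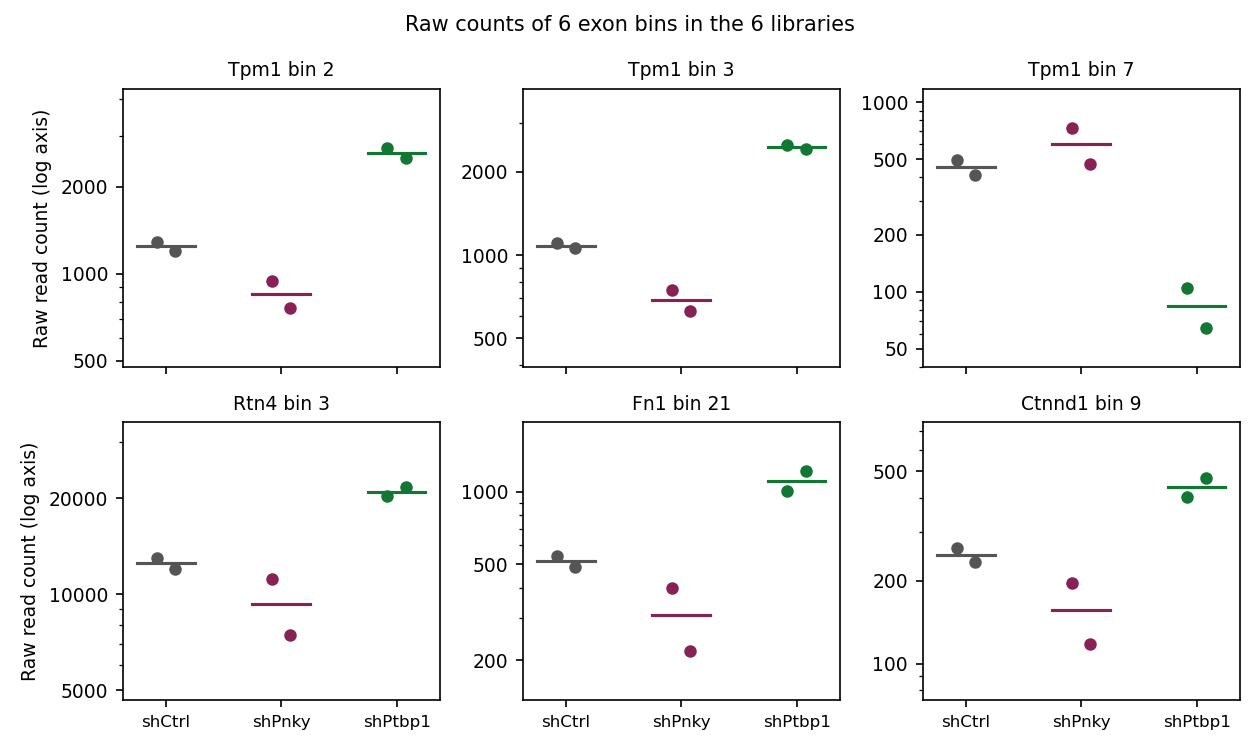
Raw read counts (vertical log axes) of 6 exon bins called in opposite directions in the 6 libraries, not scaled for depth; points are libraries and lines the means of 2. In Tpm1 bin 7 the shPtbp1 libraries hold 104 and 64 reads, the shCtrl libraries 495 and 410 and the shPnky libraries 732 and 469.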

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

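The tests in this part were chosen after the results were seen. The 17 bins called in both knockdowns with opposite directions are listed here because the authors called each in both tables with opposite signs. A test of the difference of the 2 folds passed in each, which the choice of such bins fixed beforehand, so it adds no evidence. As log2 fold in shPnky minus log2 fold in shPtbp1, from the authors' deposited tables, the difference was -0.51 for Rtn4 bin 3, -0.51 for Tpm1 bin 2, -0.61 for Tpm1 bin 3, 1.64 for Tpm1 bin 7, -0.64 for H2afy bin 3, -0.83 for Ctnnd1 bin 9, -0.73 for Fn1 bin 21, -0.59 for Limk2 bin 15, -0.74 for Plod2 bin 13 and -0.53 for U05342 bin 1. It was 0.49 for Zwint bin 7, 0.29 for Luc7l2 bin 9, 0.11 for Luc7l bin 9 and -0.15 for Araf bin 5. The smallest differences were 0.0475 for Ntrk2 bin 13, -0.0569 for Luc7l2 bin 8 and 0.0781 for Gfap bin 2. Limk2, Plod2, Zwint and U05342 are named because of these values.

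Noise of the shared controls moves both folds the same way, so it gives no opposite directions. A single library that sets the direction was tested with the share of each bin among the listed bins of its gene. The 2 groups did not overlap in 20 of 20 such shares, 18 of them in the listed direction. The choice of called bins nearly fixed this non-overlap. Over all bins with a share, it was found in 98.1% of 107 shPnky bins and 96.7% of 516 shPtbp1 bins. In 6 of the 7 bins with a share in both tables (Luc7l bin 9, Luc7l2 bins 8 and 9 and Tpm1 bins 2, 3 and 7) the groups lay apart in both listed directions. The gap was larger than the largest difference within a group, so no single library sets the direction of these shares. The choice of called bins favours such a gap, and its frequency over all bins is not given. It is therefore no evidence for a change in these 6 bins of 3 genes. With all shPnky libraries, Luc7l bin 9, Luc7l2 bin 8 and Tpm1 bin 2 did not pass the edgeR test within genes (adjusted p = 0.37, 0.31 and 0.057). The 6 bins are not separate evidence. Luc7l2 bins 8 and 9 are the only listed bins of their gene, so their shares mirror each other. In shPnky, the shares of the 3 Tpm1 bins likewise make up the whole. These 6 kept both signs in every edgeR fit without 1 library, though only Luc7l2 bin 9 and Tpm1 bin 7 had an edgeR p under 0.05 in each. In the other 11 bins a single library stays open. Of these, 10 have no share in at least 1 table, and the share of Araf bin 5 in shPtbp1 went against its listed fold. Among the 10, the share of Ctnnd1 bin 9 in shPtbp1 also went against its listed fold. That of U05342 bin 1 in shPtbp1 lay apart by 0.16 percentage points, against a largest difference within a group of 1.85. That the 2 knockdowns act in opposite ways on these exons stays a hypothesis, and a mixed effect of 1 hairpin on other transcripts was not tested.

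For the 118 bins called in both, sampling noise of the shared control libraries gave at most 2 bins in the simulated pairs. With a simulated correlation of 0.7 it gave at most 4. The simulated groups had a mean of 2.37 (shPnky) and 9.41 (shPtbp1) called bins, against 249 and 958 in the data. Lists so short could not share 118 bins, so the simulation cannot decide how much of the overlap such noise gives. A shift of the control cultures alone would give equal folds only if the knockdown cultures did not differ for other reasons. The 2 folds differed after adjustment in 51 of the 101 bins with the same sign, under the assumed covariance. That test counts only the spread between libraries, which may be technical. Differences between cultures could therefore give unequal folds as well, and the test cannot decide. In these 51 bins, as in the other 50, a shift of the controls and a shared effect cannot be told apart. Both knockdowns were set against the same 2 libraries.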

How the results depend on the processing

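Tests within genes, count tests and other scalings were chosen after seeing the data. At an adjusted p under 0.001 the called bins went from 958 to 637 (shPtbp1) and from 249 to 155 (shPnky), bins in both from 118 to 76 and genes in both from 75 to 48; the fold correlation went from 0.38 to 0.25 (permutation p = 0.029) and the genes in the same direction from 80.3% to 73.9% (34 of 46). At an absolute log2 fold of at least 1 these were 44, 5, 0 and 0, because fewer bins pass; same direction and correlation then have no value. The share of higher bins in shPtbp1, 48.0% by leading bin, was 82.1% at that fold and 54.6% over all bins, on the other side of 50%; in shPnky, 39.4% became 40.0% and 47.8%, no longer past the test. The cause was not tested. A mean count of at least 50 left 888 and 243 bins, with the shares of higher bins (46.0% and 39.4%) on the same side of the test. The edgeR test within genes called 376 of 516 shPtbp1 bins (309 to 372 without one library) and 81 of 107 shPnky bins (46 to 86; 47 without shCtrl replicate 1 and 46 without shCtrl replicate 2), where a lone library is assumed to vary like the others. No bin called with all libraries changed sign between edgeR settings, but 4 of 375 shPtbp1 calls with a listed fold had the opposite sign to it (Pdlim5 bin 6 and Tpm1 bins 4, 9 and 10). Replicates share only a number: the replicate 1 minus 2 differences of control and knockdown correlated at 0.073 (shPtbp1) and 0.033 (shPnky), and a replicate block gave 390 and 81 calls. The Ptbp1 and Ptbp2 count changes kept direction and significance in all settings run. Of 103 named bins, 87 met the stricter adjusted p, 90 the mean count and 20 the fold. No unit joined several genes, so leaving such units out moves nothing. Bin length and overlap by position were not run. Depth limits bins of few reads: 70 shPtbp1 bins have a mean count under 50.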

Other observations

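The tests in this part were chosen after the data were seen. In several genes whole runs of bins moved together. In shPtbp1, the share of Pdlim7 bin 6, of a PDZ and LIM domain protein, rose from 61.9% ± 0.81 to 85.1% ± 0.90 of the reads in its 8 listed bins, while bins 1 to 5 and the unsuffixed bin fell (SD, n = 2). In Camta1, a transcription activator, the unsuffixed bin rose from 8.56% ± 0.25 to 18.7% ± 0.42 of 10 listed bins (SD, n = 2). These genes were chosen after their values were seen.

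Neighbouring bin numbers of a gene moved in the same direction in 160 of 234 pairs in shPtbp1 (68.4%, against 54.5% of other pairs) and in 36 of 49 pairs in shPnky (73.5% against 53.8%). The permutation p was 0.0001 in each, the smallest the permutations can give.

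Genes whose unsuffixed bin was called lay on the minus strand in 74.3% of cases in shPtbp1, against 34.3% of the other called genes (two-sided Fisher's exact p = 4.87e-19), and in 71.7% against 37.2% in shPnky (p = 3.24e-05). A candidate explanation is that bins are numbered along the chromosome, so that this bin holds the 3′ end of a minus-strand gene. Among these minus-strand bins, 28 of 38 were lower in shPnky and 76 of 124 in shPtbp1 (two-sided exact binomial p = 0.0051 and 0.015). These were 73.7% lower in shPnky, against 48.1% of the other bins (Fisher's exact p = 0.0044), and 61.3% lower in shPtbp1, against 42.9% (p = 0.00015). The other 10 such bins were higher in shPnky. Usage is relative within a gene and only called bins are seen, so they cannot decide on lower 3′ coverage of every gene. A difference in coverage of all or some genes, or in the choice of 3′ ends, stays open, and no biological explanation was tested.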
